A study of Homo sapiens with 59 samples.

How the data were processed

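Gene expression was measured in 59 human colon tumor tissue samples, 1 array per sample, which the labels place in a single group. Per the labels' protocols, total RNA was isolated with a column kit and biotin-labelled cRNA was hybridised to Affymetrix arrays. The wording of that protocol speaks of cultured cells although the samples are described as tumor tissue. The deposited values are linear MAS5 signal intensity per probe set, with MAS5 named in the submitters' processing notes and its version not given in the sources used here. The deposited table held 22283 probe sets, with no missing value and none at or below 0. The mean of the middle 96% of the deposited intensity values lay between 1500.4 and 1500.5 on each array, so a common scaling of every array had been applied before deposit. The median signal of an array ranged from 535.8 to 767.4. The labels gave no batch, date, clinical variable or count of patients. The p-values therefore measure the spread between these samples, and the number of arrays limits the precision.

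Signals were transformed as log2(signal + 32), and fold changes and slopes are on that scale, which understates the change of dim genes. Of 22215 probe sets that were not controls, 19065 carried 1 gene symbol, 1043 carried several and 2107 were unnamed in the platform annotation used here; only the first kind was used. The gene identifiers of 19053 of them were in the RefSeq table of assembly GRCh38.p14, which served only for names and for which genes lie next to each other. Each gene was represented by its probe set with the highest mean, and probe sets with a mean log2 value below the 25th percentile (7.88) were left out. This left 9751 genes besides KDR, which has 1 probe set.

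Each gene was regressed on the log2 level of KDR across the tumors with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 9751 genes and a threshold of 0.05. Tumors were never divided by their KDR level. Pearson's r and Spearman's rho carried two-sided permutation p-values from 100000 permutations of the KDR values, for which 1e-05 is the smallest possible p. The r of each gene with KDR was computed again without the 2 tumors farthest from the median KDR level. Intervals are 95% percentile intervals from 10000 bootstrap resamples of the tumors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

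There were 27 gene lists, fixed before the data were examined with all other choices of the main design: endothelial, angiogenic tip cell, VEGF family, other angiogenic receptors and ligands, basement membrane, lymphatic, pericyte, smooth muscle, fibroblast matrix, macrophage, T cell, B and plasma cell, mast cell, neutrophil, tumor epithelium, normal colon mucosa, Wnt and stem cell, proliferation, hypoxia, epithelial-mesenchymal transition (EMT) and TGF-beta, immediate early, interferon, neighbours of KDR, liver, adipocyte, glia and nerve, and erythrocyte. KDR was in no list. A list was tested by the mean Pearson r of its members with KDR, with permutation p adjusted over the 27 lists. The camera test of limma set each list against the other genes with a preset correlation of 0.01 and with an estimated correlation. A score is the mean z score of the members of a list in a tumor. The fit was repeated with the fibroblast matrix score as a second covariate, without testing the members of that list.

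The genes named were chosen by a rule fixed in advance. It took the 15 genes with the highest and the 8 with the lowest r among those past the threshold whose rho had the same sign with an adjusted p under 0.05 and whose r kept its sign without the 2 tumors. It also took the leading genes past the threshold given the fibroblast score (there were none), the 3 members of each list with the largest absolute r and the member nearest 0, and a fixed set of receptors, ligands and markers. FLT4 and TIE1 were in that set and lay below the filter. Genes named outside the rule are marked as chosen afterwards where they appear.

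The procedure was tested on simulated data. For the regression on KDR over 9751 genes, 50 genes were altered at each of 4 true values of r, and 12.0% were recovered at 0.3, 84.0% at 0.5, 100.0% at 0.6 and 74.0% at -0.5, while 3 of 9551 unaltered genes were called. Each unaltered gene was shuffled over the tumors on its own, so the correlation between genes of the real data was absent from this rate. Of 400 lists without a relation, 4.0% had a p under 0.05. That check shuffled the KDR values, as the list test itself does, so such a share was set in advance and only the computation was checked. Alternatives covered pseudocounts of 1 and 128, no filter and a filter at the 50th percentile, quantile normalization, other choices of probe set, removal of the 2 tumors farthest from the median KDR level or of 2 arrays with low agreement with the others, covariates for RNA integrity, array mean and tissue composition, rank correlation, and fits within 30 and 29 tumors with a lower and a higher GAPDH 3' over 5' ratio. Leaving out each tumor in turn and the list values within those 30 and 29 tumors were added after seeing the data.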

Results

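The data comprised 59 colon tumors of 1 group, each profiled on 1 array. The stated purpose was to find genes whose expression tracks that of VEGFR-2, the receptor encoded by KDR through which vascular endothelial cells respond to VEGF-A. The design therefore implies a single comparison, that of every gene with KDR across the tumors. The median correlation of an array with the other arrays had a median of 0.905 over the arrays. It was 0.834 and 0.871 on 2 arrays more than 3 median absolute deviations below that value. No pair of arrays held mostly identical values, and the highest correlation among 1711 pairs was 0.951.

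KDR had a mean signal of 418.9 ± 184.6 (SD, n = 59). Its median was 379.5 and its quartiles 284.6 and 482.5. The lowest tumor had 175.2 and the highest 1164.7, a range of 6.65-fold. On the log2 scale 1 normal distribution described the levels better than 2 (Bayesian information criterion 98.9 against 108.8, lower being better). This gave no reason to depart from the planned treatment of the tumors as 1 continuous series. KDR had an r of -0.0887 with the GAPDH 3' over 5' ratio (permutation p = 0.505, rho -0.0231, p = 0.864), a measure of RNA integrity. The r with the ACTB ratio was -0.183 (p = 0.163, rho -0.13, p = 0.326), and with the array mean 0.226 (p = 0.086, rho 0.132, p = 0.318). Without the 2 arrays farthest from the median of the ratio or array mean in question, these r values were -0.0127, -0.0506 and 0.139. The lowest adjusted p of the 3 relations was 0.245.

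Genes of the blood vessel wall led the genes that rose with KDR. CD93, an endothelial surface glycoprotein, had the highest correlation, followed by APLNR, the apelin receptor, and GJA4, which encodes an arterial gap junction protein. MMRN2, an endothelial matrix protein that binds CD93, CALCRL, the receptor for adrenomedullin and CGRP, and ADGRF5, an adhesion receptor, completed the 6 genes with r of 0.6 or more. That count was 2 under the 50th percentile filter, 1 after quantile normalization and 2 without the 2 tumors farthest from the median KDR level. Further genes that rose were COL15A1 and NID2 of the vascular basement membrane, HEG1, an endothelial junction receptor, S1PR1, a sphingosine 1-phosphate receptor, ENG, a TGF-beta co-receptor, and RAMP3, a partner of CALCRL. LDB2, ADGRL2 and MSN, the last a linker of membrane and actin, belonged to the same leading 15. Per doubling of KDR, CD93 rose by 0.70 ± 0.10 log2 units (SE, n = 59) and APLNR by 1.16 ± 0.18.

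In all, 707 of 9751 genes were associated with KDR (limma, adjusted p under 0.05), 480 higher and 227 lower, and 2228 genes had an unadjusted p under 0.05. The smallest absolute r among the 707 was 0.362. Without the 2 tumors farthest from the median KDR level 498 of them (70.4%) still passed. All 707 kept their sign, but genes chosen for a large r seldom change sign when 2 tumors are removed. For CD93, r was 0.675 (95% interval 0.48 to 0.803) and rho 0.574, both with a permutation p of 1e-05, the smallest possible, and the limma adjusted p was 4.13e-05. APLNR had r 0.647 and rho 0.62, GJA4 r 0.647 and rho 0.619, MMRN2 r 0.644 and rho 0.539, CALCRL r 0.625 and rho 0.57, and ADGRF5 r 0.611 and rho 0.499. The other 9 of the leading 15 had r from 0.567 (RAMP3) to 0.599 (COL15A1). In a second probe set, r was 0.525 for CD93, 0.409 for GJA4, 0.451 for CALCRL, 0.453 for ADGRF5, 0.419 for HEG1 and 0.419 for ENG. The rest of the 15 had 1 probe set each. Among the 15, the highest permutation p was 2e-05 for r and 0.00011 for rho, and r without the 2 tumors lay between 0.488 (ENG) and 0.616 (APLNR). No gene had r of -0.6 or less, while 63 genes had r of 0.5 or more and 13 had -0.5 or less.

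The number of genes moved with the processing. It was 59 after quantile normalization, 193 by Spearman's rho, 215 with the array mean as a covariate and 270 without the 2 arrays of low agreement, of which 71.2%, 76.2%, 74.4% and 79.6% were higher against 67.9% in the main analysis. With the epithelial score as a covariate the number was 6 (6 higher and 0 lower), and with the endothelial score it was 0. In the 30 tumors with the lower GAPDH 3' over 5' ratio limma called 0 genes, with 766 at an unadjusted p under 0.05, and in the 29 with the higher ratio it called 362, with 1872. All 707 kept their sign after quantile normalization and with the array mean as a covariate, as genes chosen for a large r mostly would. Of the 707, 56 (7.9%) and 208 (29.4%) still passed in these settings. Leaving out the tumor with the third, the fourth or the fifth highest KDR lowered the count to 215, 308 and 399, and no other single tumor lowered it by more than 1.5 times.

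**Figure D1:**
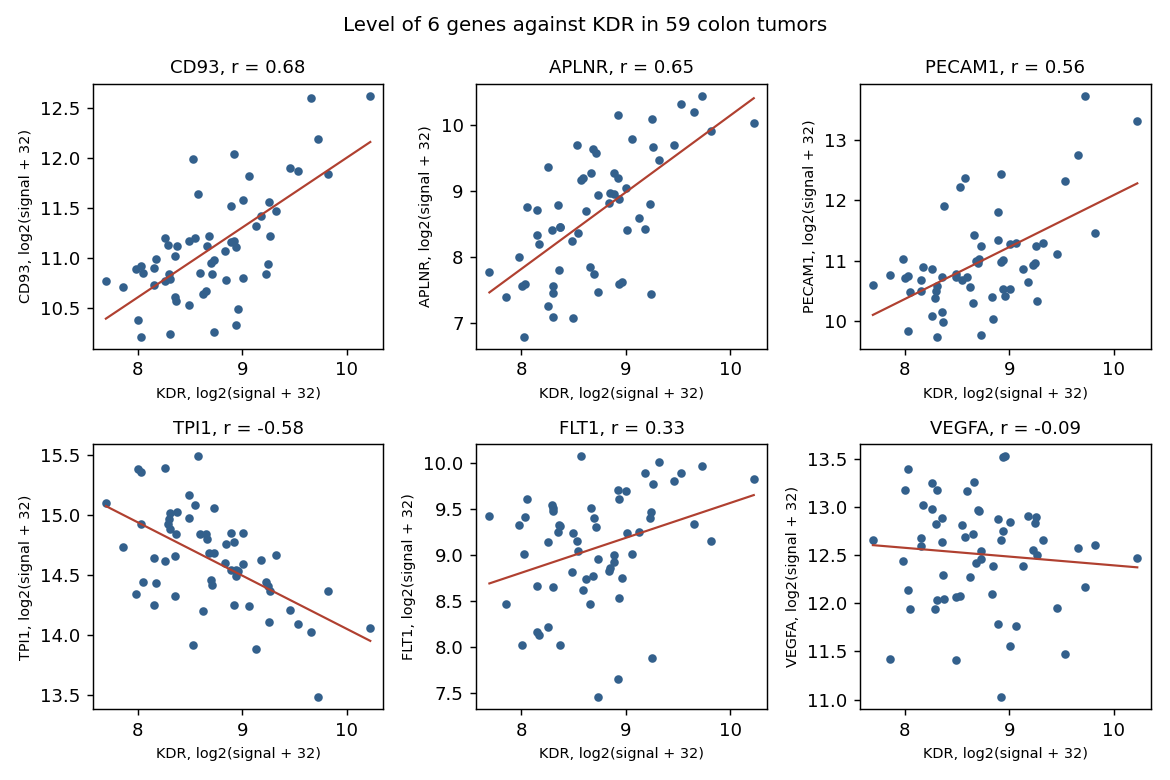
Levels of CD93, APLNR, PECAM1, TPI1, FLT1 and VEGFA (y axes) against KDR (x axes), all as log2(signal + 32). Each point is 1 of 59 tumors and the line is the least squares fit; r falls from 0.675 for CD93 to -0.0874 for VEGFA, with TPI1 at -0.579.

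Genes that fell with KDR included the glycolytic enzyme TPI1, the splicing regulator PTBP1 and the epithelial junction and envelope genes EVPL and TJP3. TPI1 fell by 0.44 ± 0.09 log2 units per doubling of KDR (SE, n = 59) with r -0.579 (95% interval -0.724 to -0.387; rho -0.539, permutation p = 3e-05). Its probe sets disagreed in size, with r from -0.579 to -0.152, and with the most variable of them in use TPI1 did not pass. PTBP1 had r -0.564, EVPL -0.561, the orphan receptor GPR35 -0.542, PARPBP, a regulator of homologous recombination, -0.539, the receptor kinase antagonist SPRY2 -0.529, the ribosome assembly factor NOP14 -0.522 and TJP3 -0.521. Over these 8 genes the highest permutation p was 3e-05 for r and 0.00059 for rho, and r without the 2 tumors ran from -0.565 (SPRY2) to -0.461 (NOP14). After quantile normalization PTBP1 (adjusted p = 0.0533), NOP14 (0.0709) and PARPBP (0.0847) did not pass. With the epithelial score as a covariate, 0 of the 220 falling genes tested passed.

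Endothelial genes rose with KDR as a group. Of 33 tested members, 23 were higher and none lower, and 28 were higher when adjusted over the list alone. PECAM1, the platelet endothelial adhesion molecule, had r 0.561 (rho 0.462), CDH5, the endothelial cadherin of adherens junctions, 0.558 (rho 0.517), CD34 0.454 (rho 0.341) and VWF, the von Willebrand factor, 0.45 (rho 0.45), with permutation p no higher than 0.00843. Over all genes, CD34 and VWF did not pass after quantile normalization (adjusted p = 0.147 and 0.0947), without the 2 arrays of low agreement (0.0571 and 0.0513) or with the array mean as a covariate (0.073 and 0.0527). By rho, CD34 had a permutation p of 0.124 when adjusted over all genes. The mean r of the list was 0.416 (95% interval 0.276 to 0.521, permutation p = 1e-05, adjusted p = 9e-05). The camera test with an estimated correlation kept the call at an adjusted p of 0.00259. The mean r was 0.369 (p = 0.00058) in the 30 tumors with the lower GAPDH 3' over 5' ratio and 0.45 (p = 1e-05) in the other 29, and the difference of 0.0808 had a 95% interval from -0.171 to 0.343. The array least like the others held the third highest KDR, with an endothelial score of 2.74 SD and an epithelial score of -4.87 SD from the mean of the tumors. Without the 2 arrays of low agreement the mean r was 0.383.

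The 10 members that did not pass over all genes were ICAM2 (r 0.345), FLT1 (0.327), ERG (0.297), NOTCH4 (0.296), ARHGEF15 (0.282), EGFL7 (0.235), MYCT1 (0.129), TAL1 (0.0683), ROBO4 (0.0285) and NOS3 (-0.222). All but ROBO4 and FLT1 were named after their values were seen. Adjusted over the list alone, the first 5 of these passed, and EGFL7, MYCT1, TAL1, ROBO4 and NOS3 did not. The probe sets of ICAM2 had r from 0.345 to 0.429, those of ERG from 0.143 to 0.401, those of ARHGEF15 from 0.0594 to 0.282 and those of TAL1 from -0.273 to 0.0858. KDR itself had r 0.68 with the endothelial score (p = 1e-05, adjusted 2e-05, rho 0.58, p = 1e-05, adjusted 4e-05, r 0.623 without the 2 tumors), 1 of 8 relations computed between scores, KDR and the array mean.

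**Figure D2:**
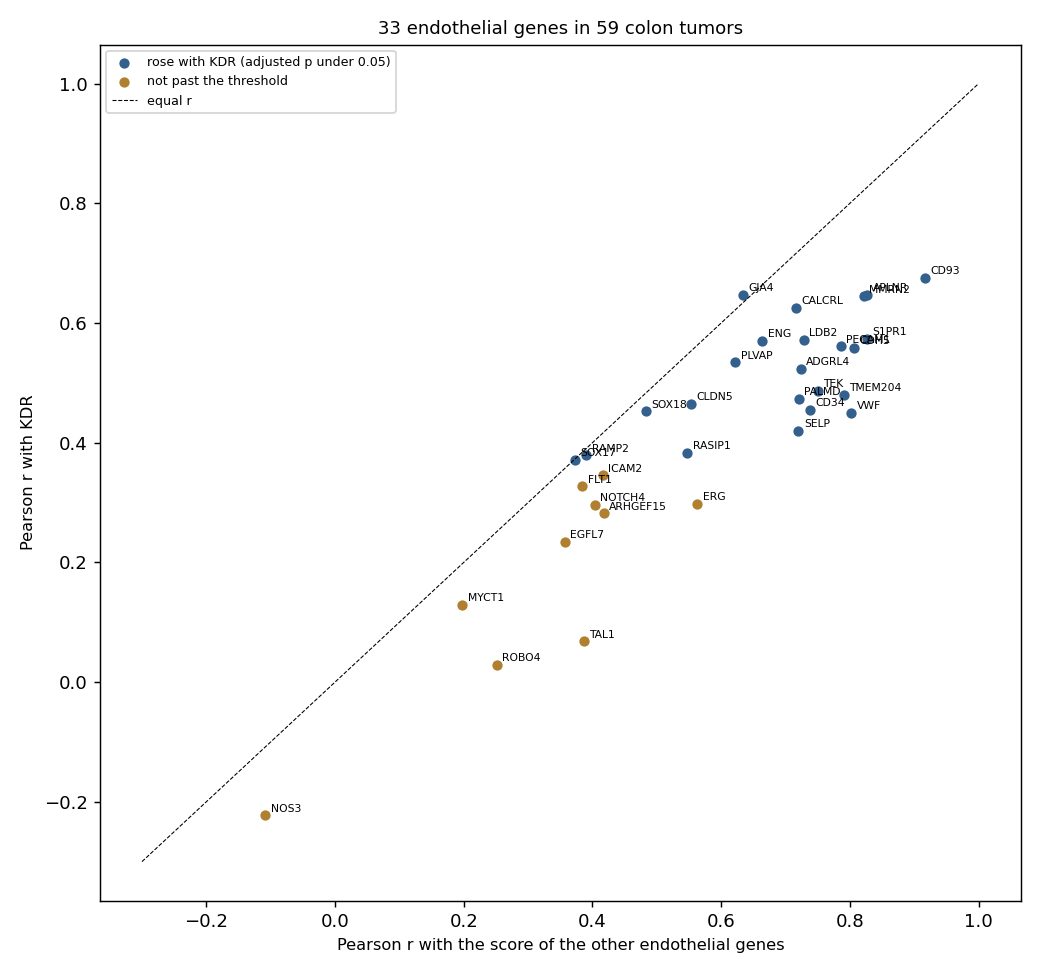
Pearson r with KDR (y axis) against Pearson r with the score of the other endothelial genes (x axis) for 33 endothelial genes in 59 tumors. Blue points rose with KDR and ochre points did not pass the threshold over all genes; the dashed line marks equal values, and CD93 lies at the upper right with 0.675 and 0.916 while NOS3 lies at the lower left with -0.222 and -0.109.

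Basement membrane genes rose with KDR nearly throughout. Of 15 members, 12 were higher, over all genes and also adjusted over the list alone. They included both chains of the main type IV collagen, COL4A1 (r 0.561, rho 0.536) and COL4A2 (0.512, rho 0.417), and the laminin chain LAMA4 (0.52, rho 0.391), with permutation p no higher than 0.00214. COL4A2 did not pass after quantile normalization (r 0.406, adjusted p = 0.0819). By rho, the permutation p adjusted over all genes was 0.0576 for COL4A2 and 0.0688 for LAMA4. The laminin chain LAMA5 had r -0.0325 (p = 0.808). The other probe sets of LAMA4 had r as low as 0.0131. The mean r was 0.403 (adjusted p = 9e-05), and the call held at an adjusted p of 0.027 with an estimated correlation. It was 0.342 (p = 0.00659) and 0.467 (p = 0.00011) in the tumors with the lower and the higher GAPDH ratio. Tip cell genes, which mark sprouting endothelium, had a mean r of 0.253 (adjusted p = 9e-05, and 0.027 with an estimated correlation). Of 14 members, 4 were higher and 7 when adjusted over the list alone: NID2, RAMP3, LAMA4 and ANGPT2 (0.412) passed over all genes, while INSR lay at -0.00409. NID2 and LAMA4 were also members of the basement membrane list, so the calls for these lists are not independent. Among tip cell genes that did not pass, ESM1 had r 0.146, PDGFB 0.128 and PGF -0.07, and 12 of the 14 members had r above 0. ESM1 and PDGFB were named after their values were seen.

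Within the VEGF receptor system, the lymphatic ligand VEGF-C and a co-receptor rose with KDR, while VEGF-A did not pass the threshold. VEGFC rose by 0.58 ± 0.13 log2 units per doubling of KDR (r 0.492, 95% interval 0.241 to 0.684, rho 0.4, permutation p = 6e-05 and 0.00181), and NRP1, a co-receptor for VEGF-A, by 0.79 ± 0.19 (r 0.476, rho 0.435, p = 0.00013 and 0.00061). TEK, the angiopoietin receptor, rose with r 0.486 (rho 0.442) and PDGFRB, the receptor of mural and stromal cells, with 0.416 (rho 0.398). After quantile normalization these 4 genes kept their sign with adjusted p of 0.0865 (VEGFC), 0.0797 (NRP1), 0.0739 (TEK) and 0.159 (PDGFRB) over all genes. PDGFRB also did not pass without the 2 arrays of low agreement (adjusted p = 0.0657) or with the array mean as a covariate (0.0877). VEGFA had r -0.0874 (95% interval -0.312 to 0.151, p = 0.51), VEGFB 0.125 (p = 0.348), NRP2 0.0995 (p = 0.451, with a change of sign to -0.0307 after quantile normalization and -0.0365 with the array mean as a covariate, and r from 0.0492 to 0.345 over its probe sets) and PGF -0.07 (p = 0.6, and 0.196 in its other probe set). The probe sets of TEK had r from 0.0661 to 0.486, those of FLT1 from 0.0475 to 0.327 and those of PDGFRA from -0.0169 to 0.342. FLT1, the sister receptor VEGFR-1, had r 0.327 and a limma adjusted p of 0.0893. PDGFRA had 0.342 (p = 0.00805), FGFR1 0.207 (p = 0.114, with its probe sets from -0.167 to 0.257) and KIT 0.159 (p = 0.23).

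Over this family of 28 genes, 8 were higher and none lower after adjustment within the family: VEGFC, NRP1, TEK, PDGFRB, ANGPT2, PDGFD, PDGFRA and FLT1, of which PDGFD (r 0.354) was named after its value was seen. The count was 4 under the 50th percentile filter, 4 after quantile normalization and 5 with the array mean as a covariate. By Spearman's rho the family adjusted p was 0.0567 for FLT1, 0.0783 for PDGFRA and 0.123 for PDGFD. As lists, the 7 VEGF family genes had a mean r of 0.195 (adjusted p = 0.00276, 2 members higher and 3 when adjusted over the list alone). The adjusted p was 0.0743 with an estimated correlation, 0.0588 after quantile normalization, 0.126 under the 50th percentile filter and 0.116 as median r. The 21 other angiogenic receptors and ligands had 0.0982 (adjusted p = 0.0259, 3 members higher and 5 when adjusted over the list alone), with adjusted p = 0.193 with an estimated correlation. That call also ended under the 50th percentile filter (adjusted p = 0.449), after quantile normalization (0.167), with the array mean as a covariate (0.107), without the 2 arrays of low agreement (0.0728) and as mean rho (0.0669).

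Fibroblast matrix genes rose with KDR, with a mean r close to that of the endothelial genes. Of 26 fibroblast matrix genes, 19 were higher, and all 26 when adjusted over the list alone. The collagen genes COL6A1 (r 0.521, rho 0.475), COL5A2 (0.52, rho 0.465), COL6A2 (0.516, rho 0.495) and COL1A1 (0.429, rho 0.452) were among them, with permutation p no higher than 0.00069, and fibronectin (FN1) had the r nearest 0, 0.259 (p = 0.0463). The mean r was 0.425 (95% interval 0.215 to 0.603, adjusted p = 0.000607, and 0.0661 with an estimated correlation). It was 0.361 (p = 0.0256) in the tumors with the lower GAPDH ratio and 0.502 (p = 0.0015) in the others. The probe sets of COL6A1 had r from 0.106 to 0.521 and those of COL1A1 from -0.154 to 0.429, and COL1A1 did not pass after quantile normalization (adjusted p = 0.0905), without the 2 arrays of low agreement (0.0513) or with the array mean as a covariate (0.0578). The endothelial mean r minus the fibroblast mean r was -0.0093, with a 95% interval from -0.184 to 0.165, so no difference was resolved. The endothelial mean exceeded the pericyte mean by 0.165 (95% interval 0.0892 to 0.245), but under the 50th percentile filter by 0.0937 with an interval that spanned 0. Intervals against basement membrane (0.013, -0.0915 to 0.119) and macrophage genes (0.0431, -0.0929 to 0.176) spanned 0.

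Other stromal lists rose as well. Smooth muscle genes had a mean r of 0.366 (adjusted p = 0.00276; 9 of 15 higher, 13 adjusted over the list alone), led by CALD1 (r 0.513), ACTA2 (0.447) and TAGLN (0.435), which encode contractile proteins. The adjusted p was 0.0743 with an estimated correlation, and other probe sets of CALD1 and ACTA2 had r as low as 0.0738 and 0.159. The mean r was 0.0937 (p = 0.584) in the 30 tumors with the lower GAPDH 3' over 5' ratio and 0.61 (p = 0.00011) in the other 29. The difference of 0.516 had a 95% interval from 0.0702 to 0.991, the only 1 of 8 lists so compared whose interval excluded 0. Pericyte genes had 0.251 (adjusted p = 0.00111; 2 of 10 higher, 5 adjusted over the list alone), with MCAM at 0.503 and RGS5 at 0.328 (limma adjusted p = 0.0836), and the list had an adjusted p = 0.0679 with an estimated correlation. EMT and TGF-beta genes had 0.305 (adjusted p = 0.00072; 5 of 15 higher, 11 adjusted over the list alone), among them the transcription factors ZEB2 (0.521) and SNAI2 (0.5) and the intermediate filament VIM (0.475), and the list had an adjusted p = 0.0661 with an estimated correlation. Lymphatic genes had 0.245 (adjusted p = 0.00141; 2 of 5 higher, also adjusted over the list alone), PDPN (0.562, with other probe sets as low as 0.15) and CCL21 (0.445). The adjusted p was 0.0718 with an estimated correlation, and under the 50th percentile filter, which left 1 member, the mean r was -0.216 (adjusted p = 0.135).

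Macrophage, neutrophil and mast cell genes rose with KDR, while the call for T cell, B and plasma cell and interferon-induced genes turned on the setting. Macrophage genes had a mean r of 0.373 (adjusted p = 0.00146; 10 of 15 higher, 13 adjusted over the list alone), with CD14, a co-receptor for bacterial lipopolysaccharide, at r 0.504, MS4A4A at 0.481 and the integrin ITGAM at 0.467 (0.0609 in its other probe set). The list had an adjusted p = 0.0743 with an estimated correlation. Neutrophil genes had 0.358 (adjusted p = 0.00072; 4 of 7 higher, 6 adjusted over the list alone), with the Fc receptor FCGR3B at 0.485, and an adjusted p = 0.0661 with an estimated correlation. Mast cell genes had 0.305 (adjusted p = 0.00196; 3 of 6 higher, 4 adjusted over the list alone), with the protease CPA3 at 0.458, and an adjusted p = 0.0743 with an estimated correlation. In the tumors with the lower GAPDH ratio the macrophage mean r was 0.361 (p = 0.0268) and in the others 0.396 (p = 0.0118). T cell genes had a mean r of 0.176 (adjusted p = 0.0569), B and plasma cell genes 0.16 (adjusted p = 0.0734) and interferon-induced genes 0.2 (adjusted p = 0.0585), with no member past the threshold in these lists, also adjusted over the list alone. The camera test with the preset correlation called all 3 lists (adjusted p = 0.00222, 0.0177 and 0.000332), and with an estimated correlation none (adjusted p = 0.273, 0.288 and 0.273). As median r all 3 passed, at 0.2 (adjusted p = 0.0388), 0.232 (0.0258) and 0.225 (0.0388). The T cell list also passed with the most variable probe set (0.183, adjusted p = 0.0449), with the mean of the probe sets (0.183, 0.0456) and with the 3' over 5' ratios as covariates (0.194, 0.0347), and the interferon list without the 2 arrays of low agreement (0.221, 0.0417). The difference between these lists and the macrophage, neutrophil and mast cell lists was not tested.

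Epithelial and proliferation genes fell with KDR as lists. Of 26 tumor epithelium genes, 7 were lower and none higher (15 lower when adjusted over the list alone), with a mean r of -0.282 (adjusted p = 0.00216, and 0.0743 with an estimated correlation). The keratins KRT18 (r -0.428, rho -0.336) and KRT8 (-0.42, rho -0.328) and the tight junction gene CLDN7 (-0.421, rho -0.364) fell, with unadjusted permutation p no higher than 0.0116. Adjusted over all genes, the permutation p of rho was 0.1312 for KRT18, 0.1465 for KRT8 and 0.0937 for CLDN7, so none passed by rank. EPCAM, the epithelial adhesion molecule, had r -0.313 (limma adjusted p = 0.116, and -0.388 with 0.0493 without the 2 tumors farthest from the median KDR level) and KRT20 0.00683. Of 29 proliferation genes, 3 were lower and 17 when adjusted over the list alone: cyclin A2 (CCNA2, r -0.442) and the replication licensing factors MCM3 (-0.42) and MCM7 (-0.373) passed over all genes. MKI67 had r -0.201 (p = 0.127), with its probe sets from -0.328 to -0.14. The list had a mean r of -0.289 (adjusted p = 0.00976, 0.148 with an estimated correlation and 0.0967 after quantile normalization). The 9 Wnt and stem cell genes had -0.192 (adjusted p = 0.001, and 0.0679 with an estimated correlation) with no member past the threshold, also adjusted over the list alone, SOX9 lying at -0.344 and LGR5 at -0.282. In the tumors with the lower GAPDH ratio the mean r was -0.195 (p = 0.0815) for epithelial, -0.199 (p = 0.191) for proliferation and -0.113 (p = 0.0663) for Wnt and stem cell genes. In the others it was -0.338 (p = 0.0129), -0.355 (p = 0.0206) and -0.243 (p = 0.00332). Without the 2 arrays of low agreement, of which the less similar had the epithelial score of -4.87 SD and the other -2.87 SD, the epithelial mean r was -0.175, the proliferation mean r -0.235 and the Wnt and stem cell mean r -0.147.

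**Figure D3:**
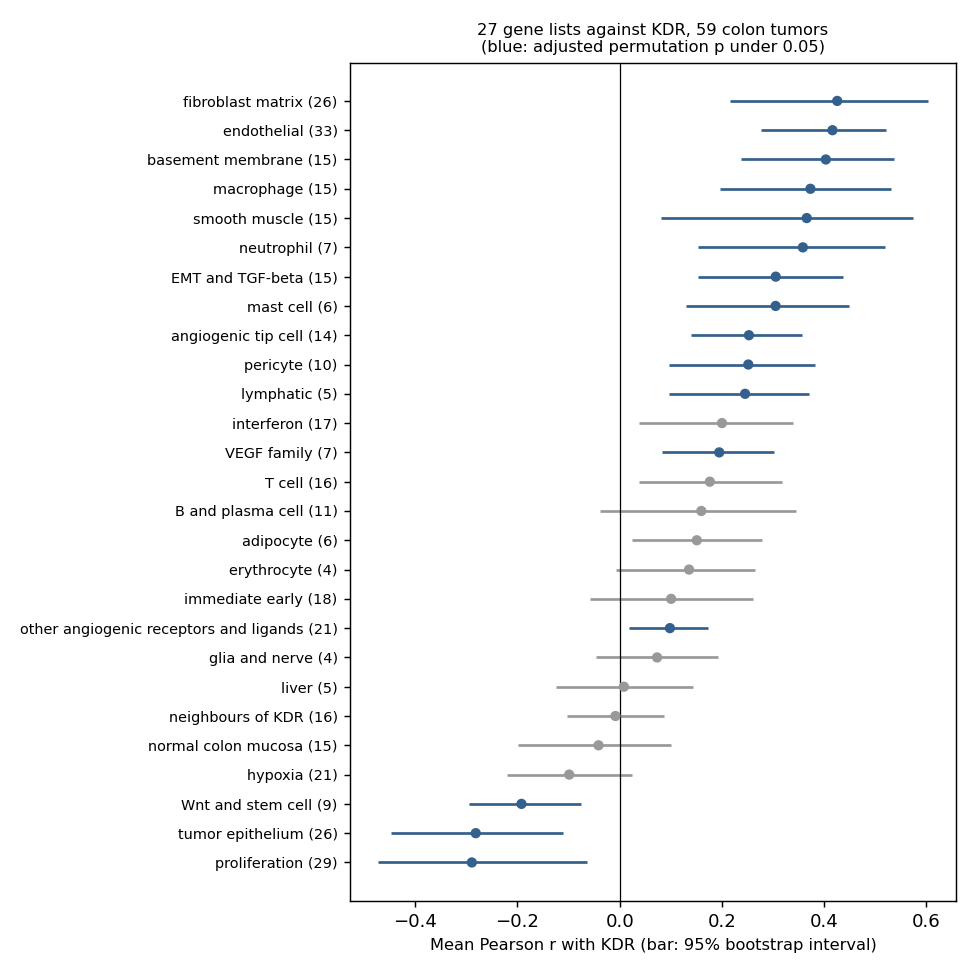
Mean Pearson r with KDR (x axis) of the tested members of 27 gene lists (y axis, number of tested members in parentheses) in 59 tumors, with 95% bootstrap intervals as bars. Blue lists had an adjusted permutation p under 0.05; they run from 0.425 for fibroblast matrix genes to -0.289 for proliferation genes.

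Endothelial genes stayed related to KDR when the fibroblast content was held constant, while no single gene passed. With the fibroblast matrix score as a second covariate, limma called 0 of 9725 genes, and 552 had an unadjusted p under 0.05. The endothelial list kept a mean partial r of 0.282 (permutation p = 1e-05, adjusted p = 0.00026). Basement membrane genes had 0.198 (adjusted p = 0.0209), tip cell genes 0.125 (adjusted p = 0.0488) and Wnt and stem cell genes -0.161 (adjusted p = 0.0209). Macrophage genes had 0.0989 (adjusted p = 0.504), smooth muscle genes 0.114 (0.504), tumor epithelium genes -0.144 (0.301) and proliferation genes -0.0715 (0.585). With the endothelial score as the covariate in place of the fibroblast score no other list passed, the lowest adjusted p being 0.656. Basement membrane genes then had 0.0127 (adjusted p = 0.984), tip cell genes -0.00266 (0.984), Wnt and stem cell genes -0.074 (0.8) and fibroblast matrix genes -0.00139 (0.99). Among single genes, CD93 had a partial r of 0.541 (limma adjusted p = 0.0883) and APLNR 0.51 (0.0939). With a pseudocount of 128, 3 genes passed: GJA4, CD93 and APLNR (adjusted p = 0.0179, 0.0396 and 0.0473).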

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

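Leaving out each tumor in turn and the list values by RNA integrity were chosen after the results were seen; the other alternatives were fixed beforehand. Of 362 alternative values of the principal results, 313 were classed as unchanged, 40 became weaker, 2 stronger and 7 changed sign. For a count of genes, unchanged meant only a number near the main one. Thus 664 and 802 associated genes, with pseudocounts of 1 and 128, were classed as unchanged against 707. Such a count does not show that the same genes passed. Without the 2 tumors farthest from the median KDR level, 498 of the 707 still passed. Of 604 others, 563 were the same, 20 weaker, 11 stronger and 10 changed sign. No paired analysis was possible because all tumors form 1 group. Unless a cause is given, the cause was not tested. The number of genes associated with KDR (707, with 480 higher and 227 lower) fell to 59 (42 and 17) after quantile normalization, 56 of them among the 707 with the same direction. It was 270 (215 and 55) without the 2 arrays of low agreement, 215 (160 and 55) with the array mean as a covariate and 193 (147 and 46) by Spearman's rho. In the 30 tumors with the lower GAPDH ratio it was 0 (0 and 0), and in the other 29 it was 362 (267 and 95); fewer samples entered both. With the endothelial score it was 0 (0 and 0), and with the epithelial score 6 (6 and 0). The 6 genes with r of 0.6 or more became 2 under the 50th percentile filter, 1 after quantile normalization and 2 without the 2 tumors farthest from the median KDR level. Given the fibroblast score, the count of 0 became 3 with a pseudocount of 128 and 1 (GJA4) with the 3' over 5' ratios as covariates.

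The 8 family genes higher with KDR became 4 under the 50th percentile filter, where fewer genes were tested, 4 after quantile normalization and 5 with the array mean as a covariate. Under that filter the lymphatic mean r was -0.216, with 4 of 5 members removed, the other angiogenic receptor mean r 0.0367, the VEGF family mean r 0.109 and the endothelial minus pericyte difference 0.0937, with an interval that spanned 0. These calls ended. After quantile normalization the calls ended for the other angiogenic receptors (0.0613), proliferation (-0.205) and the VEGF family (0.122). The call also ended for the other angiogenic receptors at 0.0851 without the 2 arrays, 0.0715 with the array mean and 0.0849 as mean rho, and for the VEGF family at a median r of 0.125. The endothelial minus fibroblast difference changed sign within its interval, to 0.00627 with a pseudocount of 128, 0.0117 under the 50th percentile filter, 0.00488 after quantile normalization and 0.00624 with the 3' over 5' ratios. Without the 2 tumors farthest from the median KDR level, the difference was -0.0268 against basement membrane and -0.00172 against macrophage genes. Among values that had not passed, the liver mean r was -0.0391 under the 50th percentile filter and as a median, -0.0698 after quantile normalization, -0.0422 without the 2 arrays, -0.0793 with the array mean and -0.0189 as mean rho. The glia and nerve mean r was -0.0675 under that filter, the mean r of the neighbours of KDR 0.0114 without the 2 arrays, and NRP2 had r -0.0307 after quantile normalization and -0.0365 with the array mean.

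Leaving out 1 tumor at a time gave 215 to 874 associated genes, 176 to 564 of them higher and 39 to 310 lower, 14 to 19 lists and an endothelial mean r of 0.385 to 0.43. Only 3 tumors lowered the count by more than 1.5 times. They held the third, the fourth and the fifth highest KDR, and the count without them was 215, 308 and 399. The first of them is the array least like the others. The precision of the KDR signal over background was not tested.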

Other observations

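Tests of the neighbours of KDR, of the endothelial genes that did not pass over the list alone, of the endothelial list with the array mean, of the share of genes with the endothelial score as covariate and of removal of single tumors, as well as relations between scores, were chosen after the results were seen; the others were written beforehand. Of 21 hypoxia genes, which include glycolytic enzymes, 3 fell (TPI1, LDHA with r -0.419 and the glucose transporter SLC2A1 with -0.38, and -0.177 in its other probe set) and 1 rose (SLC2A3, the transporter of macrophages and neurons, 0.381); adjusted over the list alone, 4 fell and 1 rose. SLC2A1 was named after its value was seen. The list had a mean r of -0.0988 (adjusted p = 0.184). The beta globin gene HBB rose with KDR (r 0.423, rho 0.368, permutation p = 0.00079 and 0.00435, adjusted over all genes 0.0237 and 0.092). The 4 erythrocyte genes had a mean r of 0.136 (adjusted p = 0.106, with 1 higher, also adjusted over the list alone).

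Immediate early genes had a mean r of 0.101 (adjusted p = 0.27), with CCN1, a matricellular protein, at 0.448 and the phosphatase DUSP1 at 0.379 both higher among 18 members, the same number as adjusted over the list alone. Adipocyte genes had 0.151 (adjusted p = 0.0708), where LPL, the lipoprotein lipase, rose (0.438) and was alone in passing the 50th percentile filter (adjusted p = 0.00168 for the list). Normal colon mucosa genes had -0.0415 (adjusted p = 0.635) and liver genes 0.0082 (0.909, with a median of -0.0391 and a mean below 0 after quantile normalization and with the array mean as a covariate), with no member past the threshold. Glia and nerve genes had 0.0731 (adjusted p = 0.31), with no member past the threshold over all genes and 2 when adjusted over the list alone, 1 in each direction. That list passed with the mean of the probe sets (0.162, adjusted p = 0.0369) and as median r (0.163, 0.0463), and had -0.0675 (0.418) under the 50th percentile filter. Genes next to KDR on the same chromosome had a mean r of -0.00839 (adjusted p = 0.894), with HOPX (0.364) and IGFBP7 (0.455), a protein of tumor vessels, higher and PAICS, an enzyme of purine synthesis, lower (-0.506, with other probe sets up to -0.179). Adjusted over the list alone, 3 were higher and 2 lower.

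Of 100 orders of the KDR values over the tumors, only 1, the real one, gave as many as the 707 genes associated with KDR. The highest other count was 1, which argues against a chance order of the KDR values. That reading assumes independent samples, and the labels gave no count of patients. With the GAPDH and ACTB ratios as covariates 89.4% of the 707 still passed, and the median absolute r hardly moved (0.421 to 0.426). Both values argue against RNA degradation, as measured by these ratios, as the whole cause. However, the 30 tumors with the lower GAPDH ratio gave 0 genes (7.86% at an unadjusted p under 0.05) against 362 (19.2%) in the other 29. The difference between these counts was not tested, so a part of RNA quality stays open. With the array mean as a covariate 29.4% still passed, as the test written beforehand required of brightness. The median absolute r went from 0.421 (quartiles 0.393 and 0.459) to 0.38 (0.348 and 0.422) and the smallest passing r from 0.362 to 0.408. After quantile normalization the median absolute r was 0.355. Because the arrays had been scaled to a common mean signal, the array mean, taken over log2 values, reflects the shape of the signal distribution and not total intensity. Whether that shape is technical or follows the tissue stays open. The array mean had r 0.591 with the endothelial score (rho 0.515, permutation p = 1e-05 and 4e-05, r 0.509 without the 2 arrays farthest from the median array mean). With the endothelial score as a covariate limma called 0 genes and 461 of 9718 genes (4.74%) had an unadjusted p under 0.05, against 22.8% without it and 5% by chance, so a candidate explanation is that KDR varied with the amount of endothelium in the tumor piece. The fibroblast score, which had r 0.709 with the endothelial score (rho 0.656, permutation p = 1e-05 for both), also left 0 genes and 5.68%. This measure therefore does not single out endothelium from stroma. By list, the fibroblast matrix genes had a mean partial r of -0.00139 (adjusted permutation p = 0.99) given the endothelial score. The endothelial genes kept 0.282 (adjusted permutation p = 0.00026) given the fibroblast score. No biological explanation other than tissue composition was tested for these genes.

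The rise of endothelial genes with KDR was set against stroma content and the array mean. Given the fibroblast score the mean partial r of the endothelial list was 0.282 (permutation p = 1e-05), and with the array mean as a covariate it was 0.375 (p = 1e-05), the smallest possible p in both. Both values argue against stroma content or the array mean as the whole cause. A mix of both, and a regional difference in vessel density, stay open and were not tested.

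The fall of genes with KDR was set against the share of tumor epithelium. With the epithelial score as a covariate 0.0% of 220 such genes still passed, as the test written beforehand required of that explanation, so a smaller epithelial share in tumors with more KDR may account for part of the fall. Their median r went from -0.416 (quartiles -0.442 and -0.391) to -0.318 (-0.371 and -0.274), and the calls ended in part because the smallest absolute r that passed rose from 0.362 to 0.519. Of all genes tested with that score, rising ones included, 11.1% still had an unadjusted p under 0.05 against 5% by chance, so the epithelial share is not shown to account for the whole fall. The fibroblast and the endothelial score as covariates also left 0 genes lower with KDR. This outcome therefore does not single out the epithelial share. The proliferation genes had a mean partial r of -0.154 given the epithelial score, -0.0715 given the fibroblast score and 0.0878 given the endothelial score. No biological explanation other than tissue composition was tested for the fall.

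The 10 endothelial genes that did not pass over all genes had a median r of 0.385 with the score of the other endothelial genes (95% interval 0.219 to 0.495), and 7 of them reached the bound of 0.3 set beforehand for dim or noisy probe sets. For the 5 that also did not pass over the list alone the median was 0.251 (0.062 to 0.447), with 2 at 0.3 or more. Both intervals include the bound, so dim or noisy probe sets stay open. The 14 tested neighbours of KDR in no other list had a mean r of -0.0453 with KDR (95% interval -0.146 to 0.0578, permutation p = 0.366), and the 13 without IGFBP7 had -0.0838 (-0.19 to 0.0278). The interval lies below 0.2, a bound set after the results were seen, which argues against copy number of the region as the main source of the KDR differences. PDGFRA (r 0.342) and KIT (0.159), neighbours that also belong to another list, were not among the 14. All 16 tested neighbours had a mean r of -0.00839 (95% interval -0.103 to 0.0874). Tissue composition can also move these values. For all 16 tested neighbours the mean partial r was -0.00675 given the epithelial score and -0.059 given the endothelial score.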
